A study of Mus musculus with 6 samples.

How the data were processed

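The series held 1 single-cell library from each of 6 groups of wild-type mice, SPF and pGF at days 0, 2 and 7 of DSS. Colon tissue was stripped of epithelium with EDTA at 37 °C, digested with Liberase TL and DNase I, and sorted by flow cytometry for CD45, and libraries were made with a Chromium 5' gene expression kit and a V(D)J kit. The deposited matrices hold raw UMI counts per gene and barcode, which per the file headers the authors made with Cell Ranger 6.1.2, for barcodes already called as cells. The submitters' processing notes also name the mm10 genome, R 4.1.3 and Seurat 4.1.1, and no value produced with R or Seurat was deposited. The V(D)J data were not analysed here.

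The matrices covered 32285 genes and 40523 barcodes, 3058, 7753 and 11629 in SPF and 1792, 9288 and 7003 in pGF at days 0, 2 and 7. Cells with at least 200 detected genes and at most 10% mitochondrial UMIs passed, and in each library the cells with the highest doublet scores (2 simulated doublets per cell) were removed at 0.8% per 1000 barcodes. The mitochondrial limit was exceeded by 22.0%, 61.1% and 8.05% of SPF and 28.1%, 19.3% and 6.41% of pGF barcodes, and 58, 186 and 989 SPF and 18, 556 and 367 pGF cells were removed as doublets. The 29130 kept cells were clustered on 2000 variable genes, 30 principal components, a graph of 20 neighbours and the Leiden method at resolution 1 with seed 0. Receptor, mitochondrial and Y-linked genes, Xist and Tsix were left out of the variable genes. No correction for differences between libraries was applied before clustering. Clusters with similar leading genes can therefore part by library as well as by cell state. No UMI of a Y-linked gene was found and Xist was present in all 6 libraries.

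Each of the 38 clusters was named from marker lists fixed before the data were examined. A name needed a mean log2 score of at least 1 (CPM + 20, against the median of clusters), at least 3 detected markers, and no more markers of another class than of its own among its 10 leading genes. Clusters of low depth also needed a marker of their own among those genes, and haemoglobin-led droplets needed 3 of theirs. This naming rule was revised several times after the clusters and shares had been seen, although the markers were not. It gave 11 named classes. The planned classes of T cells and of NK cells or other innate lymphocytes were joined as T or NK cells, because NK cells were too few in some libraries, and ILC2 stayed apart. The dendritic class rests on 7 detected markers in cluster 15 (805 cells), none of them among its 10 leading genes (H2-Aa, H2-Ab1, Retnla and Il1b are), and on 50 plasmacytoid-like cells in cluster 34. Without low-UMI clusters the SPF day 7 neutrophil share was 18.6%, and it lay between 18.6% and 38.9% over all settings. Haemoglobin-led droplets were 0.174%, 0.391% and 18.1% of SPF and 0.158%, 0.101% and 0.971% of pGF cells, and unnamed clusters 0.652%, 3.34% and 0.0415% of SPF and 0.872%, 0.736% and 0.210% of pGF cells.

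Shares of all kept and of immune cells were compared between libraries as log2 ratios, for myeloid cells (neutrophils, monocytes or macrophages, dendritic cells), B-lineage cells (B and plasma cells) and each class. Within a class with at least 100 cells in both libraries, UMIs were summed and compared as log2 of (CPM + 10), and no test or p-value was made from cells. Neutrophils passed that limit in SPF at day 7 alone, so no genes were compared within them. The genes named in the text were, per class and comparison, the 3 furthest in each direction with at least 50 CPM and 20 UMIs in the higher library. They also needed at least 0.2 of the highest level in that library among classes with at least 20 cells. Antigen receptor, mitochondrial, ribosomal protein, haemoglobin and Y-linked genes, Xist, Tsix and genes with Gm-numbered or Rik symbols were left out. Other transcripts without a gene name, such as AY036118, stayed in the ranking. Members of fixed lists were named as such. Day 2 against day 0 was compared for shares and lists, with no rule for named genes. For list medians given at bounds, a gene with 0 UMIs in a library was set at 3 counts.

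The 20 gene lists were fixed before the data were examined. The median fold of members with at least 10 CPM in a library of the pair was placed as a percentile among 10000 random lists matched in 20 expression bins, with an interval from 500 Poisson redraws. The gene Vegfa stands in both the tissue repair and the glycolysis lists, and Mx1 and Aldoa were not in the feature table. An item withheld for evaluation is not reported here. Detection rates were taken after thinning cells to 1000 UMIs. Alternatives covered filters, doublets, resolution, seed, depth, denominators, scaling (TMM), pseudocount, gene exclusion and list filter, and under TMM no named gene and no list median of at least 0.5 in size changed sign.

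Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16. On simulated data, clustering named 100% of cells right. Simulated 2-fold differences in T or NK sums had a median log2 error of 0.0873 with 98.08% inside their intervals, and 4-fold differences 0.143 and 95.83%. Of 200 unchanged lists 4.5% fell outside percentiles 2.5 to 97.5, and 100% of 50 raised lists lay above 97.5. These tests were easy, since the simulated profiles were homogeneous. Simulated cells were drawn from pooled sums of classes that the same rule had named, so their free RNA did not differ between libraries. Dendritic cells, ILC2 and haemoglobin-led droplets were not simulated, so the naming result does not cover them.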

Results

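CD45-positive cells sorted from the colon of wild-type mice were profiled by droplet single-cell RNA sequencing at days 0, 2 and 7 of dextran sulfate sodium (DSS), a polysaccharide that injures the colonic epithelium. Specific pathogen free (SPF) mice, which carry a gut flora, were set beside pseudo germ-free (pGF) mice, whose flora had been depleted with antibiotics from 4 weeks before DSS. Comparing the arms at each day asked how the colon's immune cells differed when the flora was depleted, and comparing days within an arm asked how they differed along the injury. Each of the 6 groups was 1 library, so no difference has a replicate check, and each compares libraries rather than conditions. The SPF libraries held 43949679, 37169685 and 46830975 UMIs (unique molecules) at days 0, 2 and 7, and the pGF libraries held 32870737, 52772901 and 23335071. After filtering, 2301, 2811 and 9644 SPF cells and 1262, 6932 and 6180 pGF cells were kept, with median UMIs per cell of 10486, 5461, 2778, 20492.5, 3113 and 2392 in that order. Cell classes are marker-based, so that each name means a cell like that type. Bracketed and "to" intervals are exact 95% intervals of shares (Clopper-Pearson), ratios or UMI sums (Poisson), or intervals of list medians from redrawn counts, and all cover counting error only. Folds of single genes are ratios of (CPM + 10), a scale that understates low genes, where CPM (a gene's UMIs scaled to an equal class total) is taken over all cells of a class in a library.

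Plasma cells were the largest class in both day 0 libraries, T or NK cells in pGF from day 2, and neutrophils stood out in SPF at day 7. Plasma cells, which secrete antibody, were 58.8%, 12.4% and 0.985% of kept SPF cells at days 0, 2 and 7, and 46.3%, 1.17% and 4.51% of kept pGF cells. T or NK cells were 15.9%, 23.2% and 32.9% in SPF and 19.7%, 73.6% and 72.2% in pGF. Neutrophils were 0.0435%, 1.60% and 27.1% in SPF and 0.555%, 0.635% and 1.08% in pGF. Monocytes or macrophages were 13.4%, 11.5% and 14.8% in SPF and 12.3%, 1.50% and 2.59% in pGF. B cells were 0.0435%, 0.178% and 3.04% in SPF and 0.713%, 1.33% and 11.2% in pGF. Epithelial cells, which the EDTA step and the CD45 sort should both remove, made up 23.6% of the SPF and 15.3% of the pGF library at day 2, and fibroblasts or smooth muscle cells made up 14.5% of SPF at day 2. Droplets led by haemoglobin genes were 18.1% of SPF at day 7 and 0.971% of pGF at day 7. Of the 1745 in SPF 1297 lay in cluster 7, whose leading genes also include the neutrophil genes S100a8, S100a9 and Retnlg. Saa3, Apoe and C1qb were among those of cluster 23 (292 droplets), and Gzma and Ccl5 among those of cluster 29 (119 droplets). Such droplets were counted neither as neutrophils nor as immune cells, so those shares may leave out immune cells. The cells classed as immune were 93.5%, 58.1% and 81.2% of kept SPF cells and 88.4%, 83.6% and 97.3% of kept pGF cells, so shares of immune cells are given beside shares of kept cells. These shares also depend on the sort, on a lowest UMI count of 500 per barcode (502 in pGF at day 7), on depths that differ between libraries, and on the mitochondrial limit, which 61.1% of SPF day 2 barcodes exceeded.

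**Figure D1:**
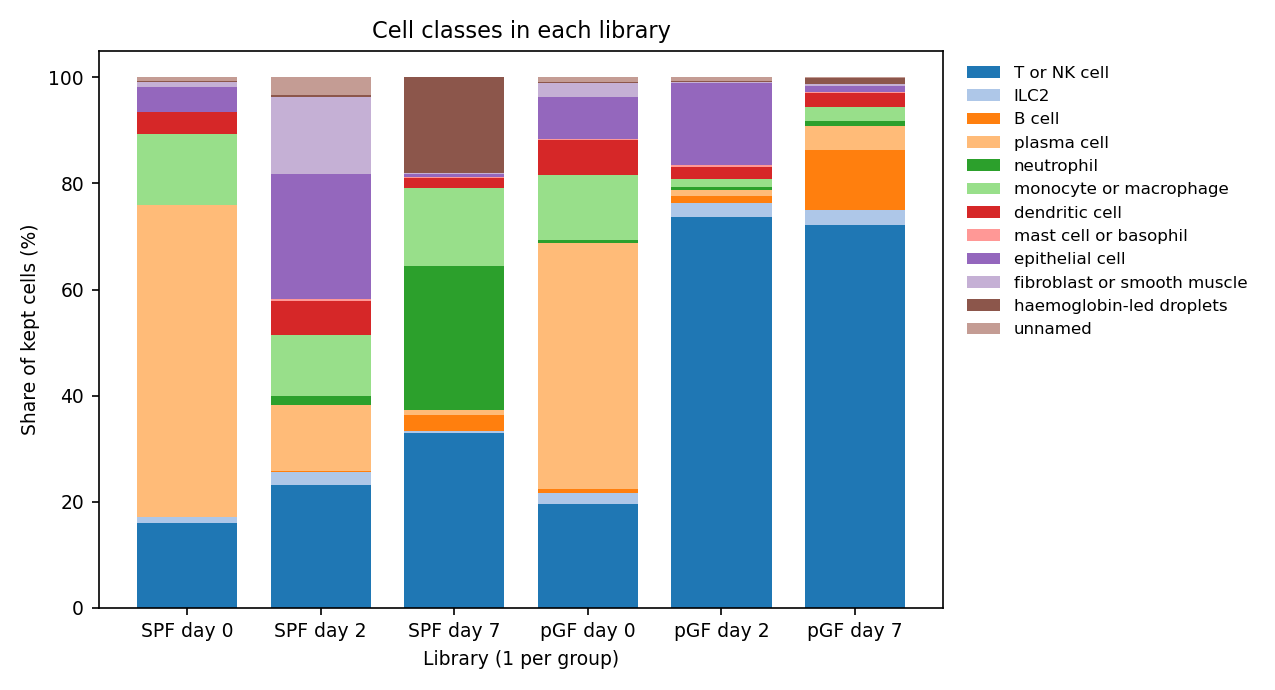
Stacked bars give the share of kept cells (%) in each class for the 6 libraries, 1 per group. Plasma cells fill 58.8% of the SPF and 46.3% of the pGF bar at day 0, T or NK cells fill 73.6% and 72.2% of the pGF bars at days 2 and 7, and neutrophils fill 27.1% of the SPF bar at day 7.

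At day 0 the pGF library, from mice already treated with antibiotics, held a myeloid share close to that of SPF and somewhat fewer B-lineage cells. Neutrophils, monocytes, macrophages and dendritic cells together were 19.6% (17.4 to 21.9) of kept pGF cells and 17.6% (16.0 to 19.2) of kept SPF cells, a log2 ratio of 0.16 (−0.08 to 0.39). B-lineage cells, nearly all plasma cells, were 47.0% (44.2 to 49.8) in pGF and 58.8% (56.8 to 60.9) in SPF, a log2 ratio of −0.32 (−0.47 to −0.18). Among immune cells these log2 ratios were 0.24 (0.0045 to 0.47) and −0.24 (−0.38 to −0.10). The myeloid difference was thus not detectable over kept cells at this depth, and it was −0.093 with at least 500 genes per cell.

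Monocytes or macrophages of the day 0 pGF library had higher levels of some inflammatory genes than those of SPF. Of 16 measured inflammatory cytokines and chemokines, 4 were at least 2-fold higher and none was 2-fold lower, with a median log2 fold of 0.80 (0.63 to 0.84) at percentile 100 of random lists. Those 4 were the T cell attractant Cxcl9 (1.11), the itaconate enzyme Acod1 (1.05), the monocyte attractant Ccl2 (1.03) and Tnf (303 CPM in pGF and 145 CPM in SPF), whereas Il1b was at −0.15 and Il6 at −0.57. The alarmin S100a9 had 154 UMIs in pGF and 0 in SPF, 13.1-fold higher, or at least 81.9-fold in CPM by its interval. The iron exporter Slc40a1 was 3.89-fold higher and the gelatinase Mmp9 3.63-fold higher. S100a9 and Mmp9 are also neutrophil markers. Neutrophils, 7 cells in pGF and 1 in SPF, were too few to enter the rule on highest class levels. Neutrophil RNA in this class thus cannot be excluded for these 2 genes or for the neutrophil granule list. Thbs1 (251 CPM in pGF and 774 CPM in SPF), Vegfa (2.99-fold) and Gpnmb (2.96-fold), all members of the tissue repair list, were lower, although that list had a median of 0.14 (−0.22 to 0.22), of the other sign with no doublets removed, with 2 of 13 members 2-fold higher and 4 lower. Homeostatic gut macrophage genes had a median of 0.39 (0.26 to 0.45), with Il10 (1.06) alone past 2-fold among 17. Genes of MHC class II presentation had a median of −0.01 (−0.08 to 0.04), neutrophil granule and alarmin genes one of 1.12 (0.96 to 1.27), interferon-response genes one of −0.12 (−0.28 to 0.00), glycolysis and hypoxia genes one of −0.16 (−0.33 to −0.05) and cell-cycle genes one of −0.60 (−0.94 to −0.32). Cluster 12 held 92.3% of this class in pGF and 82.8% in SPF, and cluster 28, whose leading genes include Thbs1 and Fn1, held 1.94% and 9.09%. The plasma cell transcript Igha stood at 15225 CPM in this class in pGF and at 24299 CPM in SPF.

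T or NK cells of the day 0 pGF library had more Ccr7 (2.60-fold), the receptor for homing to lymph nodes, and less granzyme B. Gzmb was 2.27-fold, the chemokine Ccl3 2.30-fold and the receptor Lilr4b 2.23-fold lower in pGF, while the other 8 cytotoxic genes stayed within 2-fold and the list median was −0.06 (−0.35 to 0.01). The histone gene Hist1h2ap was 2.19-fold and the microtubule regulator Stmn1 1.88-fold higher, and the cell-cycle list had a median of 0.40 (0.17 to 0.64) with no member of 11 past 2-fold. Naive and lymph-node homing genes had a median of 0.43 (0.15 to 0.82), with 1 of 7 past 2-fold. Immediate-early and heat-shock genes, which respond to tissue dissociation, had a median of −0.38 (−0.45 to −0.34). Cluster 8, led by Gzma and Gzmb, held 15.7% of the class in pGF and 29.0% in SPF, and cluster 16, led by NK genes, held 10.5% and 3.55%. The NK receptor Ncr1 was at 42.4 CPM in pGF and 8.92 CPM in SPF.

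Among day 0 plasma cells, the heavy-chain genes of the minor antibody classes differed more between the arms than the secretion machinery. Ighg1 (−3.24), Ighm (−2.79) and Ighg3 (−1.62) were lower in pGF, Ighg2c (2.43) was higher, and Igha, the dominant heavy chain, was at −0.16, with 71438 CPM in pGF and 79590 CPM in SPF. The heavy-chain median was −0.89 (−0.94 to −0.84) over 6 genes, and counts can be split wrongly among these closely related genes. After thinning to 1000 UMIs, Ighm was detected in 4.81% (3.66 to 6.19) of SPF and 3.10% (1.85 to 4.86) of pGF plasma cells. These rates lay below the 13.8% and 16.6% of T or NK cells taken as background. They therefore cannot show which cells carried the Ighm difference. Before thinning the plasma cell shares were 10.6% and 6.34%, with 168 and 4 cells left out and median UMIs of 23694 and 36591.5. The 12 plasma cell secretion genes had a median of 0.03 (0.02 to 0.05), the cell-cycle genes one of 0.25 (0.21 to 0.33) and the immediate-early and heat-shock genes one of −0.30 (−0.35 to −0.28). The interferon-induced chemokine Cxcl10 was 2.41-fold lower in pGF, the glutathione-degrading enzyme Chac1 1.83-fold lower and the chaperonin Hspe1 1.68-fold lower. The neddylation enzyme Ube2m, Hist1h2ap and the metallothionein Mt2 were 1.61-fold, 1.53-fold and 1.48-fold higher. Cluster 21, a low-UMI cluster, held 24.2% of plasma cells in SPF and 0.685% in pGF, and cluster 2 held 67.2% and 84.3%.

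At day 2 the pGF library held far fewer myeloid and plasma cells and more T or NK cells than the SPF library. Myeloid cells were 4.40% (3.93 to 4.91) of kept pGF cells and 19.6% (18.2 to 21.2) of kept SPF cells, a log2 ratio of −2.16 (−2.36 to −1.95). Monocytes or macrophages were 7.64-fold lower in pGF (log2 −2.93, −3.27 to −2.61), plasma cells were at a log2 ratio of −3.41 (−3.78 to −3.06), and T or NK cells were 3.17-fold higher (log2 1.66, 1.55 to 1.78). B-lineage cells were 2.496% (2.14 to 2.89) in pGF and 12.6% (11.4 to 13.9) in SPF, a log2 ratio of −2.34 (−2.61 to −2.07). That ratio rests on plasma cells, since B cells were 7.46-fold higher in pGF (log2 2.90, 1.62 to 4.56), from 92 pGF and 5 SPF cells. Over immune cells alone the myeloid ratio was −2.68 (−2.89 to −2.48) and the B-lineage ratio −2.86 (−3.13 to −2.59).

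Interferon-stimulated genes were higher in the day 2 monocytes or macrophages of pGF than in those of SPF. The ubiquitin-like Isg15 was 6.01-fold and Ifit2 5.71-fold higher, with Ifit3 at 2.23 and Ifit1 at 1.59 on the log2 scale. Of 24 measured interferon-response genes, 10 were at least 2-fold higher and none 2-fold lower, with a median of 0.70 (0.49 to 0.89) at percentile 100. Il22ra2, a soluble receptor that binds IL-22, had 106 UMIs in pGF and 2 in SPF, a CPM ratio of 126.9 (34.3 to 1061). Ccl5 (2.73), Tnf (1.61), Il12b (1.56) and Cxcl10 (1.51) were higher while Cxcl3 (−2.21) and Osm (−1.23) were lower, and the inflammatory list had a median of 0.27 (0.21 to 0.48), with 6 of 19 members 2-fold higher and 2 lower. The growth factor Vegfa was 8.18-fold and the membrane protein Emp1 8.66-fold lower in pGF, and Gpr35 had 2 UMIs in pGF against 120 in SPF, a CPM ratio of 0.0399 (0.00478 to 0.147). Tissue repair genes went both ways, with Thbs1 (−2.21), Fn1 (−2.15) and Chil3 (−2.13) lower and Areg (2.53) and Spp1 (1.12) higher, and a median of −0.35 (−0.65 to −0.14). The perivascular macrophage genes Lyve1 (−2.17) and Cd163 (−1.82) were lower and the Notch target Hes1 (1.63) and the complement gene C1qb (1.08) higher, so the homeostatic list had a median of −0.23 (−0.39 to 0.00). MHC class II genes had a median of 0.56 (0.47 to 0.65) with none of 9 past 2-fold, neutrophil granule and alarmin genes one of −0.85 (−1.33 to −0.42), glycolysis and hypoxia genes one of −0.13 (−0.38 to 0.18) and immediate-early and heat-shock genes one of 0.56 (0.50 to 0.66). Only 104 pGF cells stand behind these values, of which cluster 12 held 88.5%, against 48.8% of the 322 SPF cells, where clusters 5 and 28 held 27.0% and 24.2%. Igha, from plasma cells, stood at 46.1 CPM in this class in pGF and at 15219 CPM in SPF. Within cluster 12 alone the interferon median was 0.70 and the homeostatic median −0.71.

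Fewer transcripts of dividing cells were present in the day 2 T or NK cells of pGF. The replication genes Pclaf (4.91-fold), Top2a (4.78-fold) and Uhrf1 (4.67-fold) were lower in pGF, and 12 of 14 measured cell-cycle genes were at least 2-fold lower, with Mki67 at −2.16 and Stmn1 at −1.99 and a median of −1.36 (−1.50 to −1.28) at percentile 0. Naive and homing genes were higher, with 6 of 7 past 2-fold, a median of 1.20 (1.04 to 1.34), and S1pr1 at 1.72, Lef1 at 1.35 and Ccr7 at 1.20. Among genes that passed the level limits for naming, Ms4a4b (3.49-fold), the transcription factor Klf3 (3.15-fold) and Rrad (3.08-fold) had the largest higher folds. Gzmb (−1.89) and Gzma (−1.10) were lower, while the cytotoxic median was 0.08 (−0.02 to 0.19). Heat-shock genes Hspa1a (1.60) and Dnajb1 (1.47) were higher in pGF, and the immediate-early and heat-shock list had a median of 0.47 (0.30 to 0.56), the interferon list one of 0.25 (0.15 to 0.38). Cluster 31, led by Pclaf, Stmn1 and Top2a among others, held 5.67% of the class in SPF and 0.588% in pGF. Clusters 3 and 8, both led by Gzma and Gzmb, held 15.0% and 20.2% in SPF and 0.980% and 12.1% in pGF. Cluster 0 held 20.7% in SPF and 45.5% in pGF.

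At day 7 neutrophils were far fewer in pGF, as they were 27.1% (26.2 to 28.0) of kept SPF cells and 1.08% (0.841 to 1.37) of kept pGF cells. That put the neutrophil share 25.0-fold lower in pGF over kept cells and 29.95-fold lower over immune cells, from 2615 SPF and 67 pGF cells. Myeloid cells as a whole were 6.31% (5.72 to 6.95) in pGF and 43.7% (42.7 to 44.7) in SPF, a log2 ratio of −2.79 (−2.94 to −2.64), or −3.05 (−3.20 to −2.90) over immune cells. Monocytes or macrophages were 5.72-fold lower in pGF (log2 −2.51, −2.76 to −2.28). B-lineage cells were 15.7% (14.8 to 16.6) in pGF and 4.02% (3.64 to 4.43) in SPF, a log2 ratio of 1.96 (1.79 to 2.14), or 1.70 (1.53 to 1.88) over immune cells. B cells were 3.68-fold and plasma cells 4.58-fold higher in pGF, T or NK cells 2.20-fold higher, and ILC2, innate lymphocytes of the type 2 response, 8.23-fold higher, from 174 pGF and 33 SPF cells. Low-UMI clusters held part of the neutrophil class, and the SPF share was 18.6% without them and 27.8% (1632 of 5871) among cells with at least 2000 UMIs, where pGF had 0.249% (10 of 4024). Of the SPF neutrophils 56.9% lay in cluster 4, of whose 1493 cells 1487 were from that library, and 89.6% of the pGF neutrophils lay in cluster 20. Haemoglobin genes made up 0.927% of all SPF UMIs and 0.0590% of all pGF UMIs at day 7. Haemoglobin-led droplets that also held neutrophil genes were not counted in the neutrophil share.

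**Figure D2:**
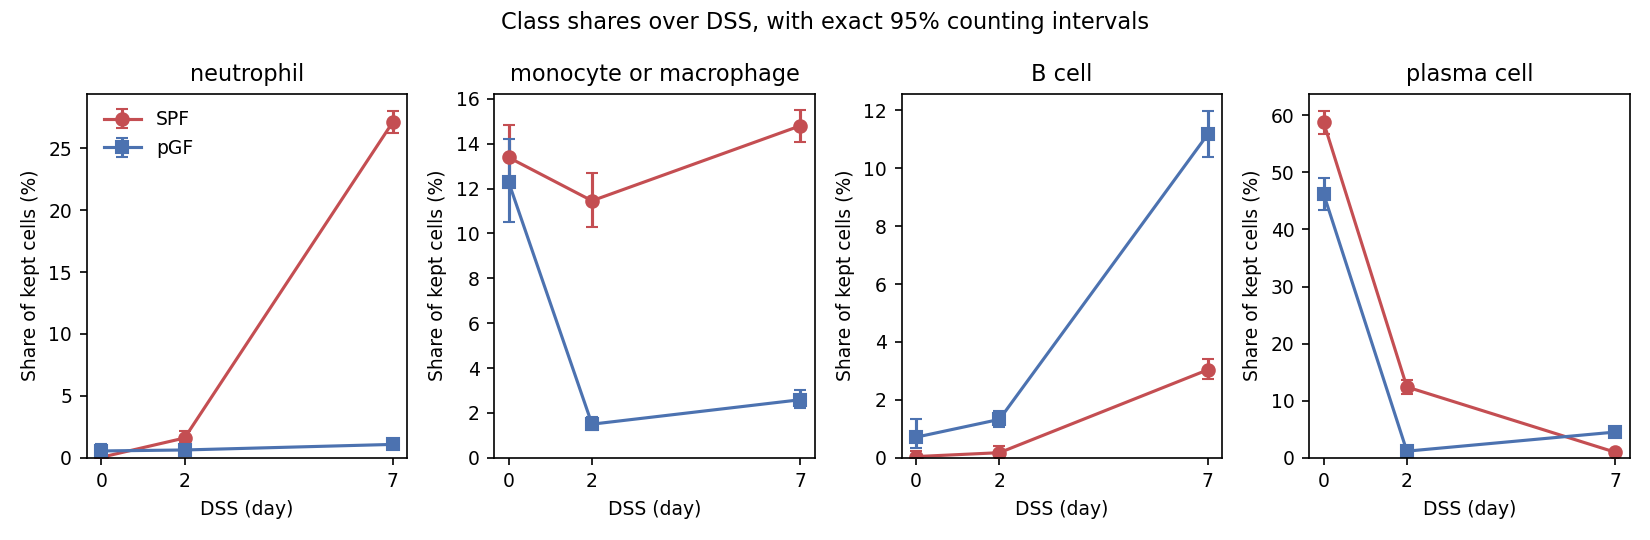
The share of kept cells (%) is plotted against the day of DSS for neutrophils, monocytes or macrophages, B cells and plasma cells, with circles for SPF, squares for pGF and bars for exact 95% counting intervals of 1 library each. Neutrophils reach 27.1% in SPF and 1.08% in pGF at day 7, and plasma cells start at 58.8% and 46.3%.

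Many inflammatory genes were lower, and many homeostatic and antigen presentation genes higher, in the day 7 monocytes or macrophages of pGF. The acute-phase gene Saa3 was 528-fold lower in pGF (21 against 180977 UMIs) and the protease inhibitor Slpi 131-fold lower. The nitric oxide synthase gene Nos2 had 0 UMIs in pGF against 7896 in SPF, 89.3-fold lower, or at least 177-fold in CPM by its interval. Of 19 inflammatory genes, 14 were at least 2-fold lower in pGF and 2 higher, with a median of −2.10 (−2.31 to −1.92), among them Cxcl3 (−5.90), Acod1 (−3.49), Il1a (−3.28), Ccl5 (−3.11), Cxcl2 (−2.44) and Il1b (−1.43). The monocyte attractants Ccl7, 16.9-fold higher in pGF, and Ccl2 (1.90) were the 2 exceptions. Homeostatic gut macrophage genes were higher in pGF, 14 of 16 by at least 2-fold, with a median of 2.28 (2.21 to 2.47), including the tetraspanin Cd81 (3.49), the selenium carrier Selenop (3.30), the fractalkine receptor Cx3cr1 (3.12) and C1qa (2.76), while Il10 was lower (−1.34). MHC class II genes had a median of 2.10 (1.99 to 2.29), 8 of 9 at least 2-fold higher, with H2-Eb1 at 2.81, H2-Aa at 2.56 and Cd74 at 2.29. Retnla and H2-M2 were 16.0-fold and 15.4-fold higher in pGF. Of 14 tissue repair genes 6 were 2-fold lower and 3 higher (median −0.73, −0.92 to −0.57), with Chil3 (−4.52), Arg1 (−4.07) and Spp1 (−3.34) low and Gpnmb (3.05) high. Glycolysis and hypoxia genes had a median of −1.36 (−1.52 to −1.23), 9 of 13 at least 2-fold lower, including Bnip3 (−1.80) and Pkm (−1.75). The interferon list had a median of −0.36 (−0.56 to −0.24), neutrophil granule and alarmin genes one of −3.37 (−3.85 to −2.88), immediate-early and heat-shock genes one of 1.28 (1.20 to 1.38) and the cell cycle list, monocyte or macrophage, pGF against SPF, day 7, one of 1.16 (0.79 to 1.31) over 5 members, which turned to −0.013 with no filter on low values.

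Cluster 5 held 91.0% of the SPF and 35.0% of the pGF cells of this class at day 7, and cluster 12 held 6.52% and 58.8%, so the values above rest on a different mix of clusters. Saa3, Cxcl2, Il1b, Cxcl3 and Chil3 lead cluster 5, and the C1q and MHC class II genes lead cluster 12. Within cluster 12 alone, the inflammatory median turned to 1.41, the MHC class II median to −0.077, the tissue repair median to 0.089 and the interferon median to 0.19, while the homeostatic (1.07), glycolysis (−0.72) and neutrophil granule (−1.64) medians kept their sign at a smaller size. The median of all genes in this comparison was 0.34, which is the level against which these medians stand. TMM scaling shifted that median by −0.57 and gave −2.70 for inflammatory, 1.94 for homeostatic, 1.55 for MHC class II, −2.04 for glycolysis and −1.41 for tissue repair genes. It gave −0.94 for interferon, −2.94 for neutrophil granule and 0.58 for immediate-early and heat-shock genes. Free RNA differed too: S100a8 was at 344 CPM in SPF T or NK cells and 1.73 CPM in those of pGF, and haemoglobin genes had a median of −3.59 in monocytes or macrophages, or −4.77 with genes at 0 UMIs set at their bound.

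The single-cell detection rates of 3 of these genes were compared after thinning each cell to 1000 UMIs, which left out 57 SPF and 9 pGF monocytes or macrophages. Nos2 was detected in 24.2% (22.0 to 26.6) of 1370 SPF cells and in 0 of 151 pGF cells (0 to 2.41), with 36.6% and 0% before thinning. Il1b was detected in 92.8% (91.3 to 94.1) of SPF and 63.6% (55.4 to 71.2) of pGF cells, against 97.6% and 69.4% before thinning. C1qa went the other way, with 10.1% (8.60 to 11.9) in SPF and 57.0% (48.7 to 65.0) in pGF, against 14.2% and 63.1% before thinning. In T or NK cells, taken as background, thinned Nos2 shares were 0.390% and 0%, thinned Il1b shares were 8.81% in SPF and 0.419% in pGF, and thinned C1qa shares were 0.423% and 0.489%. Median UMIs were 6175 in SPF and 4008.5 in pGF monocytes or macrophages, and 3163 and 2419 in T or NK cells.

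**Figure D3:**
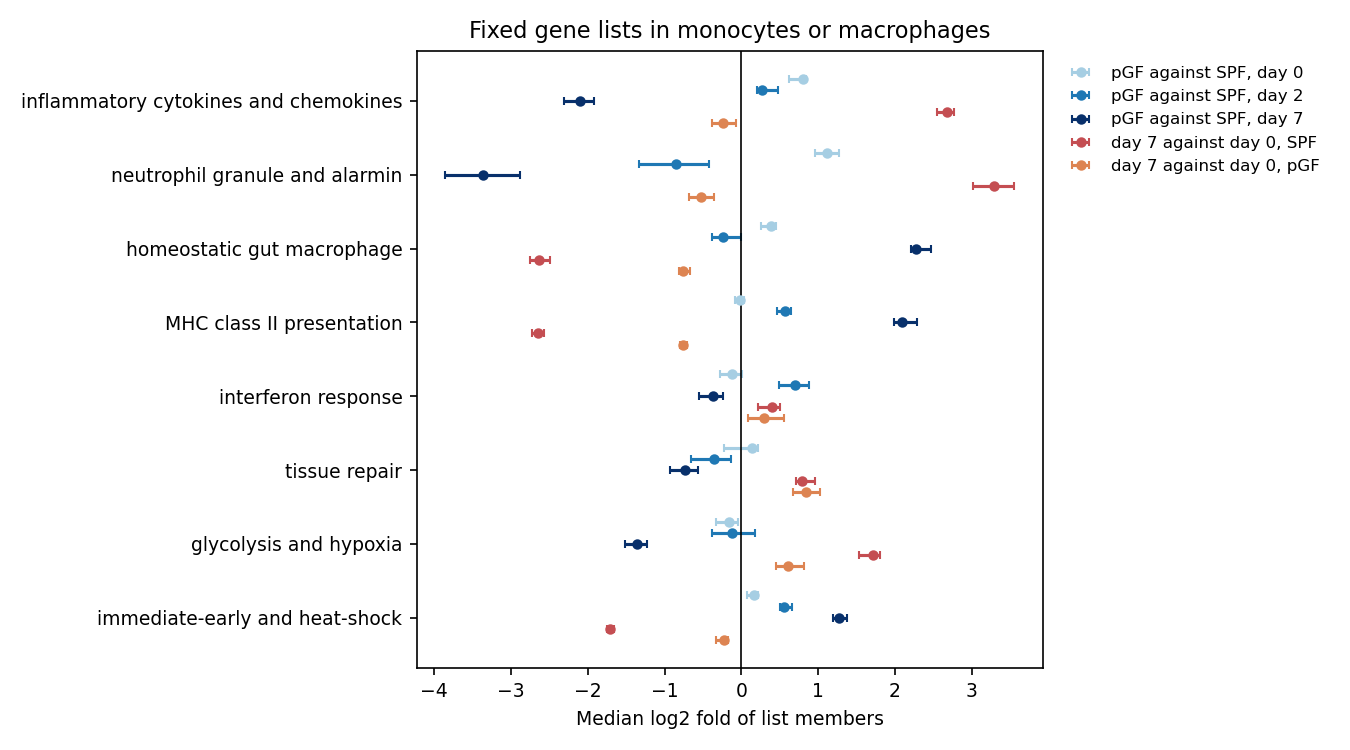
Points give the median log2 fold of the members of 8 fixed gene lists in monocytes or macrophages for 5 comparisons, with bars for the interval from redrawn counts, and 0 marks no difference. The inflammatory list stands at −2.10 and the homeostatic list at 2.28 for pGF against SPF at day 7, and at 2.68 and −2.64 for day 7 against day 0 in SPF.

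Granzymes were lower, and homing and early-response genes higher, in the day 7 T or NK cells of pGF. Gzma, a cytotoxic granule protease, was 4.77-fold lower, with 2705 CPM (2675 to 2735) in pGF and 12949 CPM (12882 to 13017) in SPF, Gzmb was 4.63-fold lower and Gzmk stood at −1.54, while the CD200 receptor family gene Cd200r2 was 3.05-fold lower. The cytotoxic list had a median of −0.58 (−0.60 to −0.55) at percentile 0, with 3 of 9 genes 2-fold lower. Naive and homing genes had a median of 1.21 (1.13 to 1.31), 6 of 7 at least 2-fold higher, with Ccr7 at 2.40, Klf2 at 1.91 and S1pr1 at 1.64. The orphan nuclear receptor Nr4a3 was 8.37-fold higher in pGF, Hspa1b 6.72-fold and Hspa1a 5.82-fold, and 7 of 16 immediate-early and heat-shock genes were at least 2-fold higher with none lower (median 0.95, 0.90 to 0.99). Regulatory T cell genes had a median of −0.65 (−0.74 to −0.52), with Tigit (−1.36) and Capg (−1.29) 2-fold lower and Icos at 0.98. The type 1 list had a median of 0.18 (0.08 to 0.24), the type 3 list one of 0.28 (0.15 to 0.40), of the other sign with no filter on low values, interferon genes one of −0.23 (−0.31 to −0.18) and cell-cycle genes one of −0.09 (−0.20 to 0.03). Thinned to 1000 UMIs, Gzmb was detected in 42.1% (40.4 to 43.9) of SPF and 12.9% (11.9 to 14.0) of pGF T or NK cells, against 49.7% and 16.8% before thinning, with 99 and 173 cells left out. Plasma cells, taken as background, had Gzmb in 2.35% (2 of 85) of SPF and 0 of 275 pGF cells at median UMIs of 17121 and 13830. They were deeper than the T or NK cells before thinning, so this background may be understated. Cluster 3, led by Gzma, Gzmb and Ccl5, held 43.8% of SPF and 4.75% of pGF T or NK cells. Cluster 8, led by the same genes, went the other way, with 0.945% and 5.56%. Of the 1764 cells of cluster 3, 1391 were from SPF day 7, so these 2 clusters may part by library rather than by cell type. Cluster 0 held 2.68% and 31.7%, and cluster 13, led by Ccr7, held 2.80% and 11.1%.

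**Figure D4:**
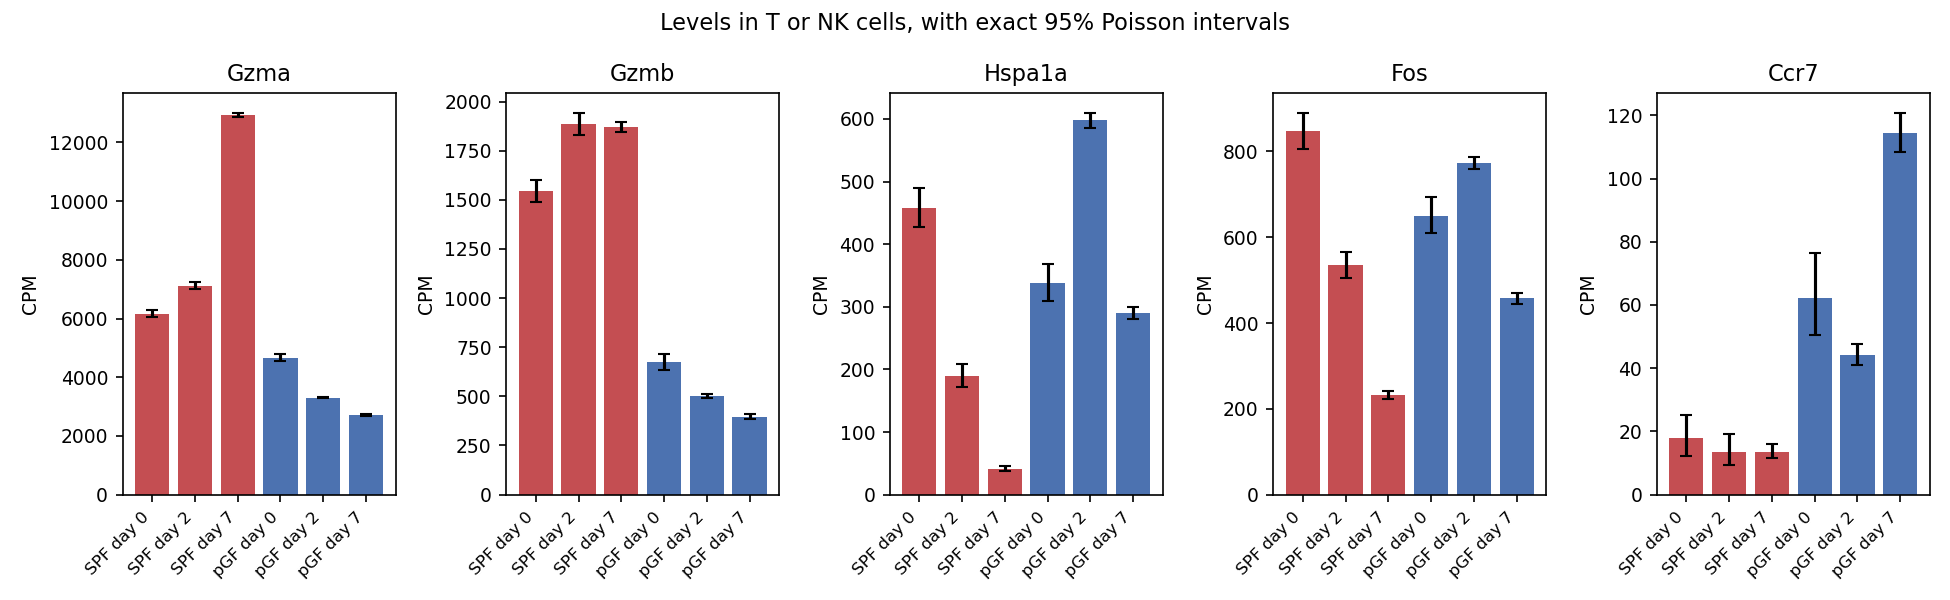
Bars give CPM of Gzma, Gzmb, Hspa1a, Fos and Ccr7 in T or NK cells of the 6 libraries, 1 per group, with exact 95% Poisson intervals. Gzma stands at 12949 CPM in SPF and 2705 CPM in pGF at day 7, and Ccr7 at 13.6 and 114.5 CPM.

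B cells of the day 7 pGF library had more Fcer2a (3.35-fold), the low-affinity IgE receptor of mature follicular B cells, than those of SPF. The arrestin-domain gene Arrdc3 was 4.94-fold and the polyamine enzyme Odc1 3.06-fold higher, and the glucocorticoid-induced Fkbp5 (5.30-fold), the phosphatase gene Ptpn22 (4.04-fold) and Hspa1b (3.42-fold) were lower. Naive and homing genes had a median of 0.59 (0.40 to 0.72) with 1 of 8 past 2-fold, and MHC class II genes one of 0.27 (0.20 to 0.36). Immediate-early and heat-shock genes had a median of −0.52 (−0.70 to −0.39), 4 of 15 at least 2-fold lower, the opposite sign to T or NK cells of the same libraries. Glycolysis and hypoxia genes had a median of −0.42 (−0.54 to −0.16), and haemoglobin genes one of −3.83 (−4.02 to −3.64), or −5.93 at bounds. These values come from 690 pGF and 293 SPF B cells, all in cluster 9.

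Along DSS in SPF, plasma cells were lower and proliferation genes of T or NK cells higher at day 2 than at day 0. Neutrophils were 0.0435% (1 cell), 1.60% (45 cells) and 27.1% (2615 cells) of kept cells at days 0, 2 and 7. The B-lineage share was at a log2 ratio of −2.22 (−2.40 to −2.05) at day 2 against day 0 and −3.87 (−4.04 to −3.71) at day 7 against day 0, or −1.54 and −3.67 over immune cells. Plasma cells made up that difference, at −5.90 at day 7, whereas B cells were at 6.13 (3.64 to 11.4), from 293 cells at day 7 and 1 at day 0. The myeloid share was at 0.16 (−0.03 to 0.35) at day 2, or 0.85 (0.66 to 1.04) over immune cells, and at 1.31 (1.17 to 1.47) at day 7, or 1.52 (1.37 to 1.67) over immune cells. The day 2 myeloid value turned to −0.084 with at least 500 genes per cell and to −0.13 among cells with at least 2000 UMIs. In T or NK cells at day 2, 10 of 14 cell-cycle genes were at least 2-fold higher than at day 0, with a median of 1.41 (1.19 to 1.52), Mki67 at 2.84, Top2a at 2.22 and Stmn1 at 2.11. The costimulatory receptor Tnfrsf4 (−1.94) and Tigit (−1.36) were lower there, with a regulatory list median of −0.35 (−0.57 to −0.20). Immediate-early and heat-shock genes had a median of −0.44 (−0.50 to −0.35) in the same cells and of −0.35 (−0.41 to −0.31) in monocytes or macrophages. In monocytes or macrophages at day 2, Chil3 (2.35), Retnla (1.89), Fn1 (1.54) and Thbs1 (1.27) were higher, giving a tissue repair median of 0.81 (0.56 to 0.95), and MHC class II genes had a median of −0.93 (−0.98 to −0.80). Plasma cells at day 2 had more Ighg2c (4.64), Ighg2b (2.73) and Igha (1.49) and less Ighm (−2.89) and Ighg3 (−2.47), with a cell-cycle median of −0.60 (−0.78 to −0.48). At day 2 Ighm was detected in 3.27% (1.65 to 5.78) of them thinned to 1000 UMIs with 13 cells left out and 6.30% before, at median UMIs of 11947. T or NK cells of that library, taken as background, had it in 14.9% at median UMIs of 2916. These rates cannot show which plasma cells carried Ighm. Epithelial genes, a sign of free RNA, were higher at day 2 in monocytes or macrophages (median 1.43, 1.14 to 1.57) and T or NK cells (1.16, 0.95 to 1.28). Cluster 12 held 82.8% of monocytes or macrophages at day 0 and 48.8% at day 2, and T or NK clusters 1 and 3 went from 1.64% and 1.37% to 17.3% and 15.0%. Of plasma cells, low-UMI cluster 21 held 24.2% at day 0 and 5.73% at day 2, and cluster 2 held 67.2% and 86.5%. All-gene medians were 0.23 in monocytes or macrophages, 0.13 in T or NK cells and 0.10 in plasma cells. TMM scaling shifted them by −0.23, −0.12 and −0.19, and in monocytes or macrophages it gave 0.53 for tissue repair and −0.64 for immediate-early and heat-shock genes.

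In SPF monocytes or macrophages the acute-phase gene Saa3 and the chemokine Cxcl3 were far higher at day 7 than at day 0. Saa3 had 180977 UMIs at day 7 and 0 at day 0, 2025-fold higher, or at least 13840-fold in CPM by its interval. Cxcl3, a neutrophil attractant, was 298-fold and the chitinase-like gene Chil3 141-fold higher. Of 19 inflammatory genes 16 were at least 2-fold higher and 2 lower, with a median of 2.68 (2.55 to 2.77), Acod1 at 5.38, Cxcl9 at 3.29, Il1a at 3.25 and Il1b at 2.12, and with Ccl7 (−4.12) and Ccl2 (−1.71) lower. Cd81 was 27.9-fold, H2-M2 19.1-fold and the early-response gene Fosb 18.5-fold lower. Homeostatic genes had a median of −2.64 (−2.75 to −2.49), 15 of 17 at least 2-fold lower, and all 10 MHC class II genes were at least 2-fold lower (median −2.64, −2.73 to −2.57). Glycolysis and hypoxia genes had a median of 1.72 (1.53 to 1.81) with 11 of 13 at least 2-fold higher, tissue repair genes one of 0.79 (0.72 to 0.96) with Arg1 at 4.17 and Spp1 at 3.37, and interferon genes one of 0.40 (0.22 to 0.50) with Gbp2 at 2.19. Neutrophil granule and alarmin genes had a median of 3.30 (3.02 to 3.56), or 4.06 with the 4 members at 0 UMIs on day 0 set at their bound, and immediate-early and heat-shock genes one of −1.71 (−1.75 to −1.65). Cluster 5 held 8.12% of the class at day 0 and 91.0% at day 7, and within cluster 12 alone the inflammatory median turned to −0.82 and the interferon median to −0.37, with −0.67 for homeostatic, −0.30 for MHC class II and 0.76 for glycolysis genes. The all-gene median was −0.19, which TMM scaling shifted by 0.37, with tissue repair genes then at 1.24 and interferon genes at 0.80. Haemoglobin genes had a median of 3.59 in this class, or 6.54 at bounds.

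T or NK cells of SPF at day 7 had lower early-response genes and higher Gzma (1.07) and Gzmk (1.15) than at day 0. Hspa1a was 9.10-fold, Nr4a3 8.85-fold and the AP-1 gene Fosl2 7.55-fold lower, and 12 of 16 immediate-early and heat-shock genes were at least 2-fold lower (median −1.46, −1.54 to −1.42). The cytidine deaminase Apobec3 was 2.68-fold, the NK receptor ligand Clec2d 2.43-fold and the chromatin reader Brd1 2.36-fold higher. The cytotoxic list had a median of 0.28 (0.09 to 0.30), the type 1 list one of −0.46 (−0.60 to −0.32) with Ifng at −1.54, and the 4 measured type 3 genes one of −0.75 (−0.95 to −0.54), which turned to 0.15 with no filter on low values. Clusters 0 and 8 held 42.9% and 29.0% of the class at day 0 and 2.68% and 0.945% at day 7, and clusters 1 and 3 held 37.0% and 43.8% at day 7. S100a8, a neutrophil transcript, was at 0 CPM in T or NK cells at day 0 and at 344 CPM at day 7, and the all-gene median was 0.10.

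Along DSS in pGF, T or NK cells filled most of the library at both later days and the myeloid share was below its day 0 level. T or NK cells were 3.74-fold higher at day 2 than at day 0 (log2 1.90, 1.72 to 2.09) and 3.68-fold higher at day 7 (1.88, 1.69 to 2.07). The myeloid log2 ratio was −2.15 (−2.40 to −1.91) at day 2 and −1.63 (−1.87 to −1.40) at day 7, or −2.07 and −1.77 over immune cells. The B-lineage log2 ratio was −4.23 (−4.49 to −3.99) at day 2 and −1.58 (−1.73 to −1.43) at day 7, or −4.15 and −1.72 over immune cells. B cells did not share that direction at day 7, when they were 15.7-fold higher than at day 0 (log2 3.97, 3.04 to 5.10), from 690 and 9 cells. Monocytes or macrophages at day 2 had higher interferon genes than at day 0, 11 of 24 by at least 2-fold with a median of 0.90 (0.70 to 1.11), or 0.59 under TMM scaling, including Rsad2 (2.01), Usp18 (1.97) and Ifit2 (1.94). Il12b (2.42) and Ccl5 (1.70) were higher and Cd163 (−1.77) and Lyve1 (−1.27) lower, with an inflammatory median of 0.25 (0.14 to 0.31), which TMM scaling turned to −0.17, and a homeostatic median of −0.66 (−0.77 to −0.36). Neutrophil granule genes had a median of −1.83 (−2.09 to −1.59), or −2.18 at bounds. In T or NK cells at day 2, naive and homing genes had a median of 0.54 (0.38 to 0.72), immediate-early and heat-shock genes one of 0.58 (0.43 to 0.69), cell-cycle genes one of −0.38 (−0.58 to −0.23), and epithelial genes, a sign of free RNA, one of 1.41 (1.23 to 1.53), or 1.60 at bounds. Cluster 12 held 92.3% of monocytes or macrophages at day 0, 88.5% at day 2 and 58.8% at day 7, and cluster 5 held 5.81%, 5.77% and 35.0%.

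At day 7 the pGF monocytes or macrophages had more Plac8 (11.9-fold), a marker of recent monocytes, and S100a4 (8.29-fold) than at day 0. The coagulation factor gene F10 had 61 UMIs at day 7 and 2 at day 0, a CPM ratio of 52.3 (13.9 to 441), and Trp53inp1, Mmp9 and Fam214a were 5.00-fold, 4.03-fold and 3.78-fold lower. Inflammatory genes had a median of −0.24 (−0.38 to −0.07), with Cxcl3 (2.45), Il6 (2.32) and Osm (1.34) higher and Cxcl1 (−1.79) lower. Tissue repair genes had a median of 0.85 (0.67 to 1.02), 6 of 13 at least 2-fold higher, with Fn1 at 2.86, Chil3 at 2.49, Gpnmb at 2.36 and Thbs1 at 1.90. Homeostatic and MHC class II genes both had a median of −0.76, with intervals of −0.82 to −0.66 and −0.79 to −0.70, and glycolysis and hypoxia genes one of 0.60 (0.46 to 0.81). All-gene medians in this class were 0.25 at day 2 and 0.19 at day 7, which TMM scaling shifted by −0.30 and −0.22, with day 7 medians then of −0.63 for inflammatory and 0.36 for glycolysis genes. T or NK cells at day 7 had more S1pr1 (2.31-fold), the receptor for leaving tissue, AY036118 (2.17-fold) and Nisch (2.13-fold). These T or NK cells had less Tigit (3.50-fold), 1 of the genes that share the symbol Ptp4a1 (2.63-fold) and the costimulatory receptor Tnfrsf9 (2.59-fold). Their naive and homing genes had a median of 0.78 (0.55 to 0.97), their cell-cycle genes one of −0.80 (−0.89 to −0.43) and their cytotoxic genes one of −0.32 (−0.51 to −0.26), and cluster 1 held 2.82% of them at day 0 and 22.5% at day 7. Plasma cells at day 7 had more Hspa1b (4.99-fold), Hspa1a (4.25-fold) and AY036118 (2.43-fold) and less of the filament gene Vim (3.71-fold), Gapdh (2.97-fold) and Hist1h2ae (2.88-fold). In them Ighm (3.70), Ighg2b (2.05), Ighg1 (1.96) and Igha (1.29) were higher and Ighg2c (−3.06) lower, with a cell-cycle median of −0.81 (−0.93 to −0.72) and a secretion median of −0.32 (−0.37 to −0.25). Ighm was in 5.82% (3.36 to 9.28) of them thinned to 1000 UMIs, with 4 cells left out, and in 8.96% before, at median UMIs of 13830, against 19.2% of T or NK cells, at 2419, taken as background.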

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

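All the tests below but the one within cluster 6 were chosen after the results were seen. Some results had opposite directions in the arms or days compared, and with 1 library per group none of these differences was tested. The myeloid share, day 7 against day 0, was at a log2 ratio of 1.31 in SPF and −1.63 in pGF. B-lineage cells, pGF against SPF, were at −0.32 at day 0, −2.34 at day 2 and 1.96 at day 7. Plasma cells alone made that turn, at −0.35, −3.41 and 2.20, while B cells were higher in pGF on all 3 days, at 4.04, 2.90 and 1.88. The B cell values rest on 9 pGF and 1 SPF cells at day 0, 92 and 5 at day 2, and 690 and 293 at day 7. In monocytes or macrophages, day 7 against day 0, the inflammatory list was at 2.68 in SPF and −0.24 in pGF, the neutrophil granule and alarmin list at 3.30 and −0.53, and the cell-cycle list at −0.98 and 0.37. Within cluster 12 alone the SPF inflammatory median was −0.82, of the same sign as in pGF, and cluster 12 held 82.8% of the SPF class at day 0 while cluster 5 held 91.0% at day 7. With no filter on low values the pGF neutrophil granule median was 0.00 and the pGF cell-cycle median had the sign of SPF. Cells outside the compared immune classes also stood out, with haemoglobin-led droplets at 18.1% of SPF day 7, and epithelial cells at 23.6% and fibroblasts or smooth muscle cells at 14.5% of SPF day 2.

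The myeloid share was lower in pGF than in SPF at day 7. Among cells with at least 2000 UMIs the log2 ratio was −3.13 (−3.33 to −2.93), which argues against low-UMI droplets as the whole cause. Among immune cells alone it was −3.05 (−3.20 to −2.90). Cells classed as immune were 81.2% of kept SPF and 97.3% of kept pGF cells at day 7. Dilution by other cells was thus larger in SPF and could only have made the difference smaller. That follows from the shares themselves and is not a separate test. The haemoglobin share of UMIs was 15.7 times as high in SPF as in pGF, so blood in the SPF tissue stays open, and bleeding is itself part of DSS colitis. A weaker recruitment of neutrophils and monocytes to injured colon when the flora is depleted may also account for it, and differences between animals or processing days cannot be separated from it.

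The plasma cell share was lower after day 0 in both arms. Barcodes rich in receptor UMIs, counted with no mitochondrial filter, were at a log2 ratio of −3.21 (−3.37 to −3.04) at day 2 against day 0 in SPF (390 of 7753 and 1420 of 3058). For such barcodes this argues against that filter as the cause in SPF. Part of the ratio comes from its denominator, since 61.1% of all SPF barcodes exceeded the mitochondrial limit at day 2 and 22.0% at day 0. Mitochondrial UMIs counted in each total, so damaged plasma cells could fail the receptor cut and be missed. In pGF, among immune cells, the log2 ratios of T or NK cells and of monocytes or macrophages at day 2 against day 0 lay 4.94 apart (4.39 to 5.50), which argues there against a loss of plasma cells alone with every other class raised alike. In SPF the gap was 0.77 (0.35 to 1.19) at day 2, beyond counting error. It was not past the bound of 1 first set for it, so it does not decide the question. For SPF at day 7 another pair, picked after the shares were seen, was used. T or NK and dendritic cells lay 2.28 (1.74 to 2.81) apart. Among SPF immune cells, days 0 and 7 held 17.0% and 40.5% T or NK cells and 4.41% and 2.17% dendritic cells. Monocytes or macrophages were 14.3% and 18.2%, and neutrophils 0.0465% and 33.4%. The classes were thus not raised alike at day 7, which argues against such a loss as the only change there. These gaps cannot weigh against a loss of plasma cells beside other changes, such as the higher neutrophil share, since any other change also parts the classes. That explanation stays open in both arms. Losses of several classes during digestion and sorting, and a biological loss during DSS, stay open. So does a loss of plasma cells alone in SPF at day 2.

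Immediate-early and heat-shock genes were higher in pGF than in SPF T or NK cells at day 7. The list was also higher in pGF in monocytes or macrophages (1.28, or 0.58 under TMM scaling) and dendritic cells (0.77), whereas B cells had a median of −0.52 (−0.70 to −0.39), which argues against a handling difference that moves every class alike. Within cluster 6 the list median was 1.07 (0.95 to 1.20), so the difference was also present inside that cluster. It held 8.9% of SPF and 13.8% of pGF T or NK cells at day 7. Clusters 1 and 3, with 37.0% and 43.8% of the SPF class, were not tested. A different mix of T or NK clusters thus stays open for the class as a whole. A handling difference that acts on most classes but not on B cells stays open, as does a biological difference between the arms.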

How the results depend on the processing

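No paired analysis was made, each group was 1 library, and no result came from a test. A fit of arm plus day over the 6 libraries, or pairs of arms by day, was not run, since both would treat arm differences that vary with the day as noise. The settings seed 1, immune cells as denominator, low-UMI clusters left out, haemoglobin-led droplets counted as myeloid, at least 2000 UMIs and cluster 12 alone were added after the data had been seen. Values are log2, and the cause of a shift was not tested unless stated. A value is counted as the same when it lay inside the counting interval of the value in the report, and otherwise as moved. Reversed means that a list median of at least 0.5 in size, a named gene, or a share ratio whose interval excluded 0 no longer had its sign.

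For the myeloid share, pGF against SPF, day 0 (0.16), at least 500 genes per cell gave −0.093. For the myeloid share, pGF against SPF, day 2 (−2.16), immune cells alone gave −2.68 and leaving out low-UMI clusters −1.95. For the myeloid share, pGF against SPF, day 7 (−2.79), a mitochondrial limit of 5% gave −3.12, one of 20% −2.96, at least 500 genes −3.15, resolution 0.5 −2.58, thinned libraries −3.09, immune cells −3.05, at least 2000 UMIs −3.13, low-UMI clusters left out −2.51 and haemoglobin-led droplets as myeloid −3.08. For the myeloid share, day 2 against day 0, SPF (0.16), at least 500 genes gave −0.084, immune cells 0.85 and at least 2000 UMIs −0.13. For the myeloid share, day 7 against day 0, SPF (1.31), mitochondrial limits of 5% and 20% gave 1.78 and 1.62, resolution 0.5 1.13, thinned libraries 1.76, immune cells 1.52, at least 2000 UMIs 1.50, low-UMI clusters left out 1.09 and haemoglobin-led droplets as myeloid 1.80. With pGF (−1.63) in place of SPF, no doublet removal and thinned libraries both gave −1.37.

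With the B-lineage share, pGF against SPF, day 0 (−0.32), at least 500 genes and at least 2000 UMIs both gave −0.18. At day 2 (−2.34) immune cells gave −2.86, and at day 7 (1.96) at least 500 genes gave 1.74 and immune cells 1.70. With the B-lineage share, day 2 against day 0, SPF (−2.22), a mitochondrial limit of 5% gave −1.93, immune cells −1.54 and at least 2000 UMIs −1.97. With the B-lineage share, day 7 against day 0, SPF (−3.87), at least 500 genes gave −3.53 and immune cells −3.67, and at least 2000 UMIs gave −1.81 in pGF (−1.58). Over all settings 118 share ratios stayed the same and 36 moved.

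Within cluster 12 alone, the day 7 macrophage medians of at least 0.5 that reversed for pGF against SPF were those of inflammatory genes (1.41, from −2.10), MHC class II (−0.077, from 2.10) and tissue repair (0.089, from −0.73), and inflammatory genes also reversed at day 7 against day 0 in SPF (−0.82, from 2.68). By construction this setting leaves out cluster 5, which held most SPF day 7 cells of the class. With no filter on low values, the reversed medians of at least 0.5 were the cell cycle list, monocyte or macrophage, pGF against SPF, day 7 (−0.013, from 1.16), the type 3 list in T or NK cells at day 7 against day 0 in SPF (0.15, from −0.75) and, at day 7 against day 0 in pGF macrophages, neutrophil granule (0.00, from −0.53) and epithelial genes (0.00, from −1.23). Over all settings 983 list medians stayed the same, 265 moved and 8 reversed, and 313 named-gene values stayed the same and 77 moved. Detection rates were compared only with those at full depth, where 38 stayed the same and 64 moved. Thinning lowers detection by construction, so that count reflects depth and is no check of the rates. List medians below 0.5 in size changed sign in 33 further cases, 10 with no filter on low values, 8 under TMM, 6 with no doublets removed, 6 in cluster 12 alone and 3 with abundant gene families left out of the total.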

Other observations

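Dendritic cells of the day 2 libraries shared the interferon difference of the monocytes or macrophages, and by day 7 it had the other sign. At day 2 their interferon-response genes had a median log2 fold of 0.93 (0.61 to 1.14) for pGF against SPF, with 9 of 23 at least 2-fold higher and none lower, led by Isg15 (3.40), Bst2 (1.77) and Ifit1 (1.72). At day 7 the median was −0.90 (−1.07 to −0.62), with 9 of 23 at least 2-fold lower and 1 higher, among them Isg15 (−3.06), Oas1a (−1.68) and Gbp2 (−1.55), while Bst2 was at 1.17. Cell-cycle genes were higher in the day 7 dendritic cells of pGF, 7 of 12 by at least 2-fold with a median of 1.36 (0.92 to 1.60), Birc5 at 2.24, Ube2c at 2.20 and Top2a at 1.98. Their glycolysis and hypoxia genes had a median of −0.69 (−0.90 to −0.49), and MHC class II genes one of −0.41 (−0.42 to −0.16). The plasmacytoid-like cluster 34, a cell type rich in Bst2, held 11.5% of the class in pGF and 4.32% in SPF at day 2, and 11.7% and 0% at day 7. Haemoglobin genes had a median of −1.51 in these cells at day 7, or −2.09 at bounds.

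Epithelial cells that passed the sort at day 2 had higher cell-cycle genes in pGF than in SPF, with Ube2c at 1.44 and Birc5 at 1.19, the 2 members past 2-fold, and a median of 0.65 (0.52 to 0.70) over 15 genes. Cluster 18, led by colonocyte genes such as Car1 and Guca2a, held 33.1% of the SPF and 19.6% of the pGF cells of this class. Within SPF, their glycolysis and hypoxia genes were lower at day 2 than at day 0, with Gapdh at −0.97, Ldha at −0.94, Pkm at −0.76 and a median of −0.60 (−0.65 to −0.52), and their cell-cycle genes had a median of −0.38 (−0.48 to −0.25). Tuft-like cluster 25, led by Dclk1 among others, held 5.57% of SPF and 12.9% of pGF epithelial cells at day 2 and none at day 0. ILC2 were 1.13%, 2.45% and 0.342% of kept SPF cells and 2.06%, 2.68% and 2.82% of kept pGF cells at days 0, 2 and 7. Their log2 ratio of pGF against SPF was 0.13 (−0.28 to 0.55) at day 2, and at day 7 they were 8.23-fold higher over kept and 6.87-fold higher over immune cells.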
